A study of Mus musculus with 18 samples.

How the data were processed

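Single-cell RNA sequencing with 10x Genomics chemistry was carried out on cells of 3-week-old mice, with 9 gene expression libraries and 9 matched hashtag libraries (18 samples). A hashtag is a barcoded antibody that marks all cells of one pool before pools are mixed, so that each cell can be traced back to its pool. Per the labels' protocols, mice were perfused with buffer before the organs were taken, brain was homogenised mechanically and separated on a Percoll gradient, and dura and colon were digested with collagenase and DNase I. How lung, spleen, thymus and blood were prepared is not given in the sources used here.

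The deposited values are whole-number UMI counts per gene and cell barcode, made with Cell Ranger 7.0.0 per the file headers and aligned to mm10 per the submitters' processing notes. They had not been normalised. Each matrix held 32285 genes and 4 hashtag features, and no other column was left aside. Gene coordinates came from a GENCODE annotation of the same build (GRCm38), in which 32158 gene identifiers (99.6%) were found. A reference table in the labels assigns each hashtag to a genotype and a sex. It lists brain library 1 with the tags of blood and dura and brain library 2 with those of lung and colon, while the tags counted in the matrices were the reverse. The counted tags were used, so that the first hashtag set holds brain library 2, blood and dura, the second brain library 1, lung and colon, and the third brain library 3, spleen and thymus. The 4 tags of a set stood for WT male, WT female, 15q male and 15q female pools. A hashtag pool mixes several mice. The labels give the same numbers of WT and 15q mice for dura and blood (7 and 10), thymus and spleen (7 and 7), and lung and colon (7 and 5). The numbers for brain (21 and 22) equal the sums over these tissue pairs. Libraries of one set, its brain library included, may therefore share mice. If so, the 3 sets would be the independent units, and an exact permutation of signs over 3 units cannot go below p = 0.25. The p-values measure the spread between libraries, the 9 pairs may not be independent, and p-values over libraries may be too small.

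Barcodes were kept with at least 500 UMIs, at least 300 genes and under 10% mitochondrial UMIs. A barcode was given to a pool where it had at least 10 tag UMIs and its top tag held at least 75% of them. Of 40477 barcodes, 2446 were hashtag doublets, 25 others failed the filters on cells and 38006 were kept, of which 38003 had a pool. The remaining 3 had too few tag UMIs and entered the values per library but not those per genotype. Doublets between cells of one pool cannot be seen by hashtags, and removing cells ranked highest by Scrublet (at 0.8% per 1000 barcodes) was tried as an alternative, because its automatic threshold marked almost no cells in several large libraries. The tag sex was checked against Xist and Y-linked genes, and 36 of 36 pools matched their tag. A match asked only which of Xist and the summed Y-linked genes was higher. In colon the Y-linked sum was 32.0 CPM in the 15q female pool, 1.87 in the WT female pool and 212 and 200 in the 15q and WT male pools. In lung the female pools held 10.8 (15q) and 0.562 (WT), while the 15q female pools of spleen and thymus held 0. Some mixing of male cells or RNA into female pools is therefore not excluded.

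Cells were normalised, reduced to 2000 variable genes and 30 principal components and clustered with the Leiden method (15 neighbours, resolution 1) in scanpy 1.11.5 under Python 3.11.15, with igraph 0.11.9 and scikit-learn 1.9.0. No integration between libraries was applied. Clusters were named from 25 marker lists fixed before the data were examined. A name needed at least 3 raised markers (log2 fold of at least 1, detected in at least 5% of cells). The thresholds of this scoring were set after the data were seen. Of 29 clusters, 26 were named and 3 stayed unnamed. Cells of 10 clusters were called gamma-delta T-like (20878 cells), 9 of them type 17-like.

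UMIs of gamma-delta T-like cells were summed per library, or per library and genotype, with at least 10 cells per sum. Sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood test) with Benjamini-Hochberg adjustment at 0.05. Brain (3 libraries) was compared with the other tissues (6 libraries). The 15q against WT tests had the library as a block, since both genotypes of a pair were processed in one library. The deviations of the 2 members of each pair correlated at 0.344 to 0.957 over all libraries and 0.333 to 0.555 in brain, which is the check of that pairing. Sex was not a term of these tests. The female share of cells in WT and 15q was 21.6% and 39.7% in blood and 51.7% and 22.9% in brain library 3. It was close in lung (53.2% and 50.2%) and colon (50.4% and 51.9%). Sums were compared over 16 gene lists with limma 3.58.1 camera (preset correlation of 0.01), and with an estimated correlation and fry beside it. The ratio of the duplicated region between genotypes was tested by exact two-sided permutation of signs over libraries. Tissues with 1 library have no replicate, so their values are CPM with exact Poisson 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. All these intervals cover counting error only. For receptor genes, each cell was also thinned to 1000 UMIs.

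The test script was checked on simulated counts with known changes. In the design of brain against other tissues, edgeR called 10% of 50 genes changed 2-fold, 68% of those changed 4-fold and 90% of those changed 8-fold. For 15q against WT over all libraries it called 80% of genes changed 1.5-fold and 96% of those changed 2-fold, and in brain 47.9% and 81.2%. For the interaction these shares were 28% and 56%. False calls were 2 of 10284 unchanged genes, 14 of 10153, 20 of 7198 and 7 of 10142 in the same order.

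Up to 15 genes in each direction were to be named per test, among those past the threshold with a mean of at least 20 CPM and the same direction in every pair (or, for brain, every brain library beyond every other library). Where fewer than 5 passed, the 5 smallest p-values are given as values. Also named were 2 to 4 members of each gene list with the largest changes, the members of the duplicated region, the 6 genes per tissue with the highest ratio to any other tissue after adding 10 CPM (at least 30 UMIs), and the 3 highest and 3 lowest genes by genotype per tissue. Predicted genes, ribosomal, mitochondrial, immunoglobulin and T cell receptor genes were not named by this rule. It was fixed before the data were examined.

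Alternatives fixed at the same time were DESeq2 1.42.0, no filter on low counts, a stricter filter on cells (1000 UMIs, 500 genes, 5% mitochondrial), a gate on Trdc in place of clusters, Scrublet, thinned sums, leaving out each library, a tag share of 90%, no block, total UMIs for scaling, WT cells alone and Leiden resolutions of 0.5 and 2. Leaving out the second hashtag set, using male or female pools alone, using type 17-like clusters alone, adding an unnamed thymic cluster, using the hashtag set as a batch term, means without colon, male and female pools apart in single tissues and subtracting the gamma-delta share from B-like cells by Il17a were added after the data were seen. Other software was numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, umap-learn 0.5.12 and matplotlib 3.10.9.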

Results

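Gamma-delta T cells, sorted per the labels for a receptor with the Vgamma6 chain, were profiled in 3-week-old WT and 15q dup mice, from brain, the dura around it, colon, lung, spleen, thymus and blood. The 15q dup mouse carries a copy of a chromosome 7 segment whose human counterpart is duplicated in a neurodevelopmental syndrome. Brain was covered by 3 libraries and each of the 6 other tissues by 1. The labels give 21 WT and 22 15q mice for brain, 7 and 10 for dura and for blood, 7 and 7 for thymus and for spleen, and 7 and 5 for lung and for colon. The 9 libraries held 38006 cells after filtering and 207828502 UMIs in all barcodes. Brain library 2 was the deepest (55467971 UMIs, 6912 cells), followed by blood (55005060 UMIs, 8714 cells), lung (38125434 UMIs, 8610 cells) and colon (37395892 UMIs, 10341 cells). Dura (7144067 UMIs, 1079 cells), spleen (6583381 UMIs, 1130 cells) and thymus (5032262 UMIs, 649 cells) were smaller. Brain library 3 (1707102 UMIs, 298 cells) and brain library 1 (1367333 UMIs, 273 cells) were the smallest. Of gamma-delta T-like cells, dura held the fewest (169), followed by brain library 1 (180) and brain library 3 (198).

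Gamma-delta T-like cells filled colon, spleen and lung but were a minority in brain library 2, dura and blood. They made up 99.1% of cells in colon (95% interval 99.0 to 99.3), 88.9% in spleen (86.9 to 90.6) and 82.6% in lung (81.8 to 83.4). Brain library 1 held 65.9% (60.0 to 71.5) and brain library 3 66.4% (60.8 to 71.8), against 6.97% (6.38 to 7.60) in brain library 2. Dura held 15.7% (13.5 to 18.0) and blood 14.4% (13.6 to 15.1). The 3 libraries with these low shares are those of the first hashtag set, so the share follows the set as well as the tissue, and the sort can set it. Other cells of brain library 2 were CD8 T-like (22.5%), CD4 T-like (18.8%), NK-like (12.6%), ILC2-like (9.92%) and regulatory T-like (4.88%), and 15.8% stayed unnamed, as did 19.5% in blood, 17.4% in brain library 3 and 10.3% in dura, most of these in cluster 3 (11.1%, 17.9%, 16.1% and 8.16% in the same order). ILC2-like cells, type 2 innate lymphoid cells, were the main class of dura (35.3%), and NK-like cells that of blood (59.3%). B-like cells were 29.3% of brain library 1, 8.72% of brain library 3 and 6.66% of lung. In thymus 35.6% of cells (31.9 to 39.4) were gamma-delta T-like and 64.3% stayed unnamed. Most of the unnamed cells lay in cluster 7 (55.8% of thymus cells), with raised Rag1, Rag2, Ptcra and Dntt, genes of developing thymocytes, and with UMIs of the gamma-delta genes Trdc in 77.8%, Tcrg-V6 in 65.4% and Sox13 in 63.3% of its cells. At a Leiden resolution of 2 the gamma-delta T-like share was 78.3% in thymus and 55.8% in colon. At that resolution a cluster of 2838 cells stayed unnamed, though its best list was type 17-like with 10 raised markers, Trdc and Tcrg-V6 among them. Another of 1689 cells was named ILC3-like (type 3 innate lymphoid cells), though type 17-like in the first scoring step. Areg and Odc1 were among the top 10 genes of each. The lower colon share may thus reflect the naming of clusters.

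**Figure D1:**
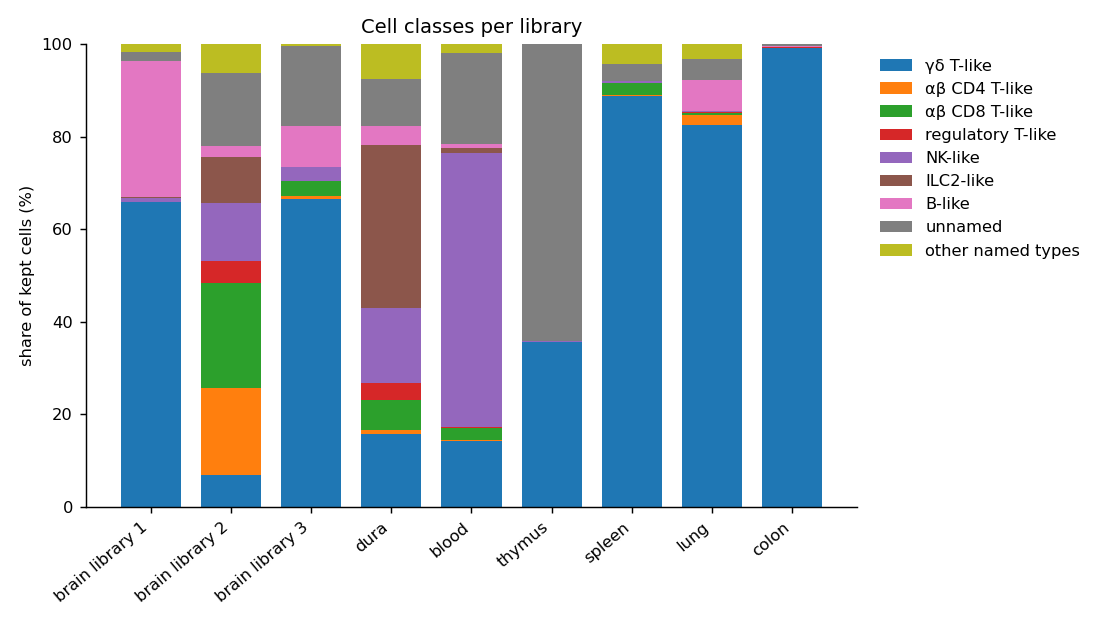
Share of kept cells (percent, y axis) in each named class for each of the 9 libraries (x axis). Gamma-delta T-like cells reach 99.1% in colon and fall to 6.97% in brain library 2.

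Transcripts of the sorted receptor chain were most frequent in spleen, brain library 1, thymus and colon and least frequent in blood. Tcrg-V6, which encodes the variable segment of the sorted chain, had a UMI in 98.5% of gamma-delta T-like cells in spleen, 95.6% in brain library 1, 92.6% in thymus, 91.5% in colon and 81.5% in lung. It was seen in 63.3% in dura, 52.0% in brain library 3, 51.7% in brain library 2 and 18.9% in blood. After each cell was thinned to 1000 UMIs the shares were 80.5% in spleen, 77.9% in thymus, 76.3% in brain library 1, 69.7% in colon, 65.2% in lung, 48.5% in dura, 43.4% in brain library 3, 38.8% in brain library 2 and 14.5% in blood. Thinning left out 84 cells in colon, 16 in lung, 6 in dura, 3 each in brain library 1, brain library 2 and blood, 2 in spleen and 0 in thymus and brain library 3. Trdv4, the delta segment paired with it, was found in 96.1% of these cells in colon, 93.9% in brain library 1 and 90.7% in spleen, but in 55.0% in thymus and 19.4% in blood. Tcrg-V4, a segment of another gamma-delta subset, was found in 37.2% in blood, 34.8% in brain library 3, 24.9% in brain library 2 and 4.15% in colon. Over all libraries Trdv4 was also found in 43.4% of ILC2-like cells, 14.6% of NK-like cluster 1 and 4.62% of B-like cells. Its share in blood is thus near that of other cells. Tcrg-V4 was found in 1.42% of NK-like cluster 1 and 1.54% of B-like cells. Median UMIs of the gamma-delta T-like cells were 2923 in colon and 3671 in lung. In B-like cells, which should lack the gene, Tcrg-V6 was seen in 5.76% of 573 cells in lung (median 2451 UMIs), 21.1% of 19 cells in colon (median 2170 UMIs), 2.56% of 78 cells in blood (median 6498.5 UMIs) and 1.25% of 80 cells in brain library 1 (median 3140.5 UMIs).

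**Figure D2:**
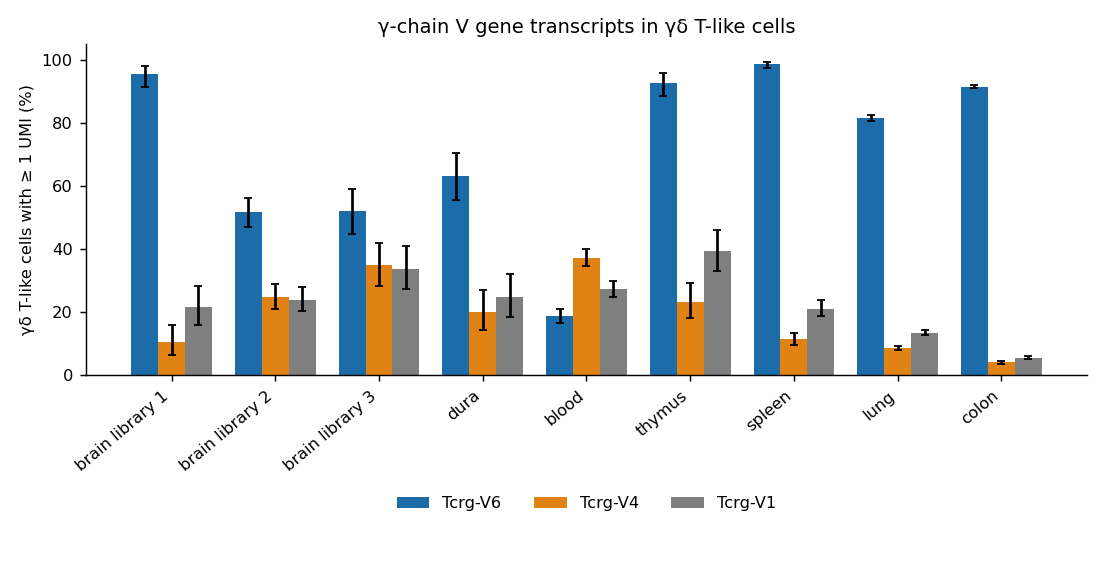
Share of gamma-delta T-like cells (percent, y axis) with at least 1 UMI of each receptor segment in each library (x axis), with exact 95% intervals. Tcrg-V6 lies at 98.5% in spleen and 18.9% in blood, and Tcrg-V4 at 37.2% in blood.

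Genes of the duplicated segment were higher in cells labelled 15q in every library of the first and the third hashtag sets, and not in those of the second. The summed CPM of the region list gave a mean log2 ratio of 15q over WT of 0.39 ± 0.31 (SD, n = 9 libraries, higher in 8 of 9, exact two-sided permutation p = 0.0195). In the 6 libraries of the first and the third sets it was 0.58 ± 0.10 (SD, n = 6, higher in 6 of 6, exact p = 0.03125, the smallest this design allows), and in the second set -0.0059 ± 0.051 (SD, n = 3). The second set was left out after these ratios were seen, so the p-value over 6 libraries is no separate test. Libraries of one set may share mice, so both p-values may be too small. Ube3a, a ubiquitin ligase gene on chromosome 7 from 59228750 to 59311536 (mm10), had a log2 ratio of 0.71 (95% interval 0.58 to 0.83) in the first and the third sets. Herc2, another ubiquitin ligase gene (56050196 to 56231800), had 0.57 (0.43 to 0.71), Snrpn, an imprinted splicing gene (59982495 to 60140219), 0.80 (0.20 to 1.43), and Atp10a, a phospholipid transporter gene (58656166 to 58829420), 0.21. The imprinted gene Ndn had 34 UMIs in 15q against 1 in WT cells, and Mkrn3 12 against 5. Oca2 had 2 against 0 UMIs, Gabrg3 2 against 1, and Gabra5, Snurf, Magel2 and Peg12 had 0 in both. Of the flanking genes, Nipa1 had 1.73 (0.85 to 2.72), Cyfip1 0.26 (0.036 to 0.48), Nipa2 0.08 (-0.12 to 0.30) and Tubgcp5 -0.05 (-0.32 to 0.22). The second set parted by sex. Its pools labelled male gave 0.43 ± 0.15 (SD, n = 3) and its pools labelled female -0.51 ± 0.067 (SD, n = 3), against the direction of the label. Female pools of the other sets gave 0.42 ± 0.28 (SD, n = 6, higher in 5 of 6). All genotype values are therefore given by label, and those of lung, colon and brain library 1 carry this contradiction.

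**Figure D3:**
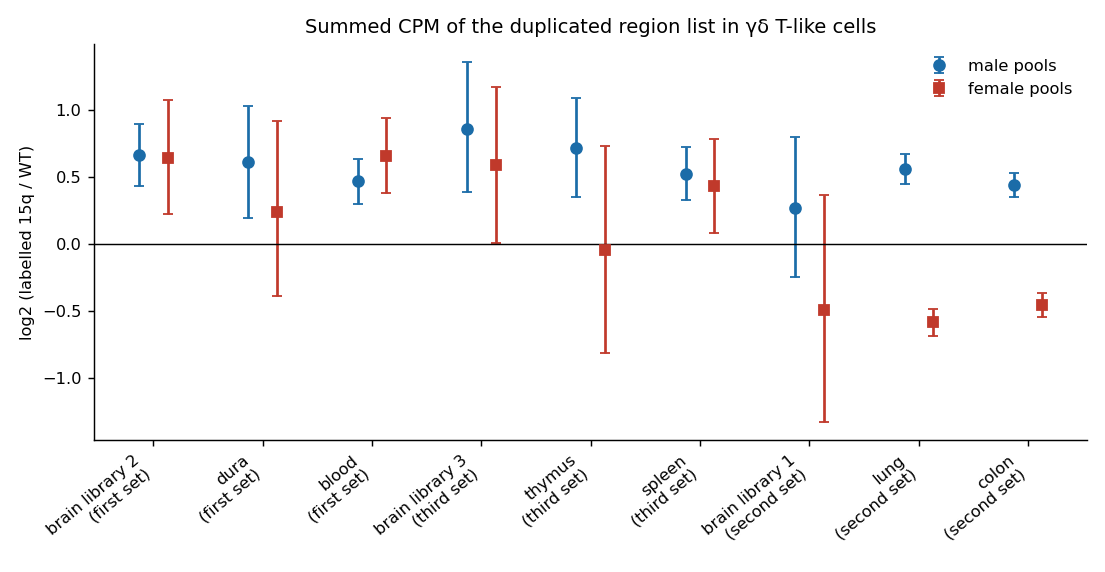
Log2 ratio of labelled 15q over WT of the summed region list (y axis) in gamma-delta T-like cells per library and per sex pool (x axis), with exact 95% intervals. The female pools of the second hashtag set lie below 0 (mean -0.51), while their male pools lie above 0 (mean 0.43).

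**Figure D4:**
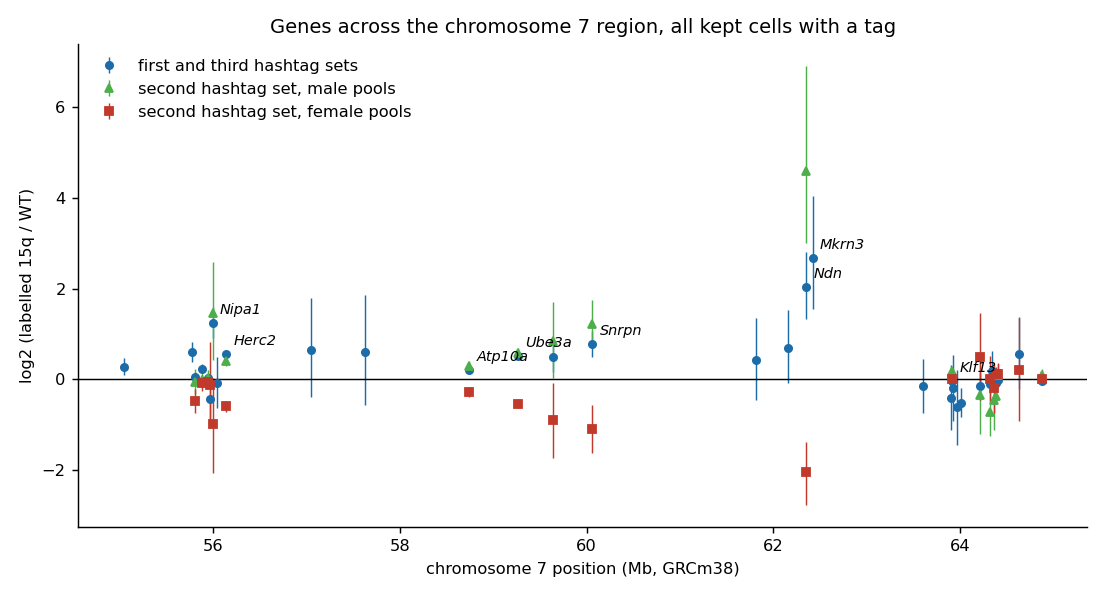
Log2 ratio of labelled 15q over WT (y axis) of genes along chromosome 7 from 54 to 65 Mb (x axis, mm10) in all kept cells, for the first and the third hashtag sets and for male and female pools of the second. Herc2 and Ube3a lie at 0.57 and 0.53 in the first and the third sets and at -0.59 and -0.53 in the female pools of the second.

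Gamma-delta T-like cells from brain held less transcript of immediate early genes than those of dura, blood, lung and colon, and about as much as those of thymus and spleen. This comparison asks how the brain cells differ from those of other sites. The immediate early and stress list summed to 4369 ± 706 CPM in brain (SD, n = 3) and 8417 ± 4798 in the other tissues (SD, n = 6; thymus 4041, spleen 3680, mean without colon 6978), with 17 of 19 tested members lower (camera adjusted p = 0.0011, adjusted p = 0.777 with an estimated correlation). Fos, a transcription factor gene induced within minutes of stimulation, was at 5.88 ± 3.17 CPM in brain and 325 ± 371 elsewhere (196 without colon), Junb at 132 ± 22.2 and 2211 ± 2203, and Dusp1, a phosphatase gene of the same response, at 29.6 ± 5.26 and 439 ± 418. Of the tissue residency list 13 of 15 members were lower (adjusted p = 0.00145, adjusted p = 0.777 with an estimated correlation). Its sum of 1992 CPM in brain lay below dura (3207), lung (4258) and colon (8576) and above blood (1691), thymus (1700) and spleen (1732). Among its members were Nr4a3, an orphan nuclear receptor gene, at 2.60 ± 0.29 CPM against 81.8 ± 127 (34.0 without colon), and Rgs1, a regulator of G protein signalling, at 42.7 ± 15.98 against 768 ± 1073 (344 without colon). The residency list also holds Nr4a1, an early receptor-signalling gene, and Hspa1a is on both lists. Its result may therefore not be independent of the immediate early list. Of the cell cycle list 16 of 19 were lower (adjusted p = 0.00145, adjusted p = 0.777 with an estimated correlation), led by Cenpa, a centromere histone gene, at 19.6 ± 6.53 CPM against 81.4 ± 78.0 (52.4 without colon, 15.97 in thymus). Its sum of 980 CPM in brain lay above dura (821). Of the checkpoint and costimulation list 9 of 10 were lower (adjusted p = 0.0177, adjusted p = 0.777 with an estimated correlation), with Ctla4, an inhibitory receptor gene, at 8.07 ± 7.88 CPM against 215 ± 385 (60.7 without colon), and Tnfrsf9 at 4.74 ± 4.48 against 144 ± 306 (19.5 without colon). Its sum of 654 CPM in brain lay above blood (614), thymus (583) and spleen (376), and the mean of the other tissues fell from 1290 to 846 without colon. Of the type 1 and cytotoxic list 15 of 18 were lower (adjusted p = 0.0492, adjusted p = 0.777 with an estimated correlation), but it did not pass camera with the hashtag set as a batch term (adjusted p = 0.128) or in type 17-like clusters (0.0657), and its sum of 885 CPM in brain lay above dura (430) and spleen (556). Among its members were the granzyme genes Gzma at 2.63 ± 3.81 CPM against 167 ± 264 (62.3 without colon, 1.79 in dura, 1.82 in spleen) and Gzmb at 5.13 ± 3.86 against 109 ± 167 (44.96 without colon). Fry gave adjusted p = 0.585 for the first 4 of these lists and 0.793 for the last. B-like cells of the same libraries showed the immediate early list at 4873, 4899 and 5038 CPM in brain libraries 1 to 3, 5438 in dura, 6893 in blood, 9435 in lung and 10489 in colon (19 cells). Their Il17a put the RNA of gamma-delta T-like cells in them at 7.12% in lung and 17.9% in colon of the level of those cells, and the list less that share was at 8530 and 7695 CPM. Across the 7 libraries with both classes the list correlated (r = 0.962, exact permutation p = 0.000992, rho = 0.893, exact permutation p = 0.0123, r = 0.809 without colon and lung), with r = 0.926 (exact permutation p = 0.00258) less that share and r = 0.932 without colon. It was the only relation of this kind computed, and a hashtag set holds too few libraries for a value of its own.

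**Figure D5:**
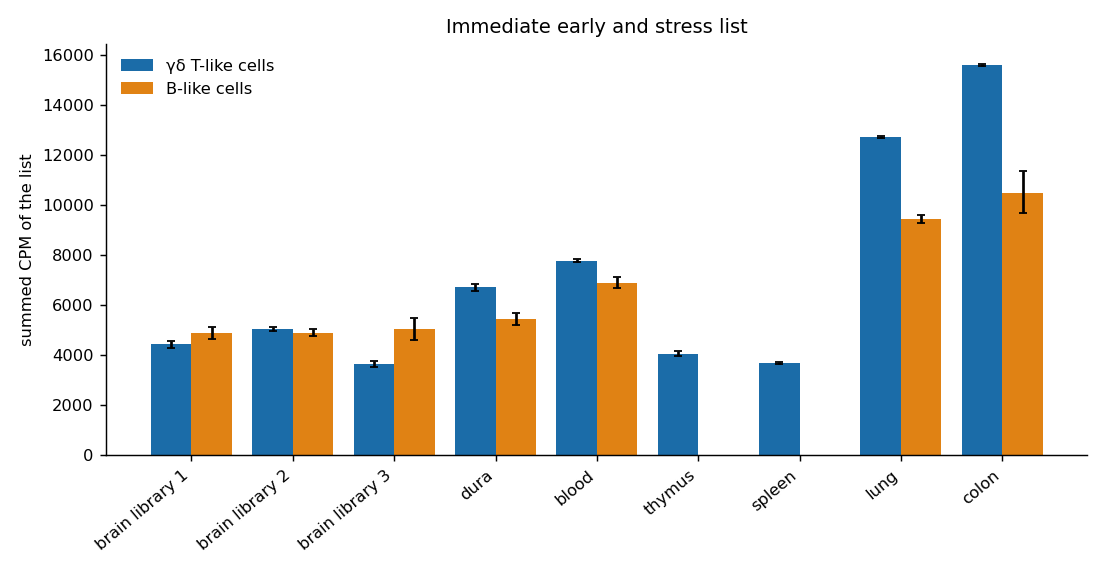
Summed CPM of the immediate early and stress list (y axis) in gamma-delta T-like and B-like cells of each library (x axis), with exact Poisson 95% intervals. Both classes are highest in colon (15610 and 10489 CPM) and lung (12707 and 9435 CPM).

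The type 17 list, the program of interleukin 17 producing cells, was not lower as a group (11 members higher and 13 lower, adjusted p = 0.462). Il23r, the receptor for its driving cytokine, was at 434 ± 30.8 CPM in brain (SD, n = 3) and 317 ± 219 elsewhere (SD, n = 6), from 136 in blood to 731 in dura. Il17a itself was at 6.70 ± 8.29 CPM in brain and 585 ± 828 elsewhere (295 without colon), from 8.65 in thymus to 2037 in colon, and Il17f at 3.89 ± 2.94 against 17.0 ± 15.4. The other lists did not pass camera. Of 14 glycolysis genes 11 were lower (adjusted p = 0.23), with Hk2, hexokinase, at 7.37 ± 2.11 against 18.2 ± 14.6 CPM. Of 15 interferon genes 13 were lower (adjusted p = 0.23), with Isg15 at 23.2 ± 18.8 against 73.2 ± 67.0. Of 23 oxidative phosphorylation genes 14 were lower (adjusted p = 0.23), with Sdhb at 109 ± 5.56 against 147 ± 21.5, and of 14 cytokine genes 10 were lower (adjusted p = 0.23), with Ifng at 0.106 ± 0.183 against 5.55 ± 7.16. Areg, a growth factor gene of this list, had 0 UMIs in all brain sums, while colon held 4328 CPM. Of 13 naive and recirculation genes 12 were lower (adjusted p = 0.462), with Bach2 at 40.1 ± 25.9 against 86.5 ± 57.1, and of 19 chemokine receptor and integrin genes 12 were lower (adjusted p = 0.597). Of 8 neurotransmitter receptor genes 4 were higher (adjusted p = 0.487), with Ramp1, a coreceptor for the neuropeptide CGRP, at 712 ± 69.8 against 421 ± 226. Of 8 lipid genes 3 were higher (adjusted p = 0.779), with Abca1, a cholesterol exporter, at 20.3 ± 0.928 against 8.72 ± 7.12. Of the region list 3 of 4 and of its flank 2 of 3 members were higher (adjusted p = 0.779 and 0.462).

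By single genes, 0 of 10634 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (552 at an unadjusted p under 0.05, smallest adjusted p = 0.744), and DESeq2 called 0 (709 unadjusted). The 5 smallest p-values are given as values. Ccr4, a chemokine receptor gene, was at 4.19 ± 2.14 CPM in brain (SD, n = 3) and 19.3 ± 5.98 elsewhere (SD, n = 6), a log2 difference of -2.05 ± 0.42 (SE). Pfdn4, a prefoldin subunit gene, had -1.11 ± 0.24 and Myl4, a myosin light chain gene, -3.65 ± 0.90. Zfp740, a zinc finger gene, was at 42.2 ± 2.71 against 26.7 ± 3.67 CPM, and Zmynd8, a chromatin reader gene, at 54.7 ± 1.76 against 36.9 ± 3.89. Most brain cells of this class fell in cluster 9 (87.2%, 72.6% and 64.6% in libraries 1, 2 and 3), as did those of dura (91.7%), while cluster 6 was the largest in blood (53.9%) and thymus (43.3%), 21 in spleen (58.3%), 10 in lung (49.0%) and 27 in colon (49.9%).

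Areg and Tnfrsf9 were among the genes with the highest ratio of colon to any other tissue. Without replicates, these values describe single libraries and have no replicate check. In colon Areg, the EGF receptor ligand amphiregulin, reached 4328 CPM (4306 to 4351) against 191 in lung, the next highest, Tnfrsf9, a costimulatory receptor gene, 768 against 38.2, Odc1, the enzyme that starts polyamine synthesis, 2433 against 360, Ece1 481 against 44.8, Litaf 268 against 21.3 and Zeb2 201 against 19.4. Lung led in Nr4a1, an early receptor-signalling gene, at 678 CPM against 323 in colon, in Zfp36, an RNA decay factor gene, at 510 against 205 in dura, and in Nfkbid at 173 against 59.2 in colon. B-like cells of lung held 527 CPM of Nr4a1, 830 of Zfp36 and 176 of Nfkbid. Cd74, at 92.6 CPM, was at 17424 in B-like cells of lung, and Muc1 was at 12.02 and Hspa1a at 10.3. Thymus led in Ly6a, a surface antigen gene induced by interferon, at 1324 CPM (1266 to 1383) against 262 in spleen, in Rtp4 (135 against 45.2), Usp18 (51.9 against 10.6), Plac8 (182 against 67.2), Arpp21 (27.9 against 5.09) and Id3 (363 against 151). Blood led in Tsc22d1 (156 CPM against 37.1 in lung), Rras2 (190.0), Klhdc2 (154), Rab3ip (137), Pde2a (70.1) and Xdh (53.7). NK-like cells of blood held 319 CPM of Pde2a, 94.9 of Xdh, 153 of Klhdc2 and 149 of Rras2. Spleen led in Rom1 (126 CPM against 46.1 in lung), Matn2 (78.7), Rap1gap2 (66.3), Olfr60 (37.3), Car5b (29.0) and the B cell gene Cd79b (173 against 96.0 in blood). Dura led in Eno1b (221 CPM against 105.3 in spleen), Chst11 (162), Tex14 (86.9), Stab2 (80.6), Lrp1b (40.3) and Slc24a3 (38.5). ILC2-like cells of dura held 725 CPM of Stab2 and 184 of Eno1b, and fibroblast-like cells 123 of Slc24a3. The brain libraries were each compared with the 6 other tissues and not with one another. Fgfr2 led brain library 1 (3541 CPM) and brain library 3 (962), and B-like cells of the same libraries held 3046 and 560 CPM, so it was not particular to gamma-delta T-like cells. Brain library 1 also led in Filip1l (1126), Jarid2 (616), Il1rapl1 (202), Kcnip1 (138) and Olfr77 (34.2), brain library 2 in Klhl9 (62.3), Plekhg2 (59.4), H6pd (48.3), Espn (37.2), Cnr2 (20.3) and Setbp1 (18.7), and brain library 3 in Afm (216), Ly6c2 (113), Gucy1b2 (103), AC154200.1 (34.5) and Man2c1os (29.2). Several of these were not particular to gamma-delta T-like cells. B-like cells of brain library 1 held 842 CPM of Filip1l, 435 of Jarid2, 163 of Il1rapl1, 60.4 of Kcnip1 and 36.2 of Olfr77. Those of brain library 3 (26 cells) held 190 of Afm, 85.4 of Gucy1b2, 37.9 of Ly6c2, 28.5 of AC154200.1 and 0 of Man2c1os. NK-like cells of brain library 2 held 95.2 CPM of Setbp1, and CD8 T-like cells of brain library 3 held 1170 of Ly6c2 (10 cells). Brain library 1 held about as much Afm (211), Gucy1b2 (106) and AC154200.1 (34.2) as brain library 3.

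Over all tissues, cells labelled 15q held less Slc15a2 than WT cells, a difference that lies in the female pools. Slc15a2, which encodes a peptide transporter (chromosome 16, 36750177 to 36784962), was at 58.4 CPM in WT and 36.1 in 15q cells (mean of 9 libraries), a log2 change of -0.87 ± 0.095 (SE, lower in 9 of 9 libraries, adjusted p = 2.4e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In male pools alone its change was 0.12, and it was not called with thinned sums, with no replicate block or without the second hashtag set. Xcl1, a chemokine gene, was at 3.57 CPM in WT and 8.10 in 15q cells (log2 change 0.81 ± 0.15, higher in 8 of 9 libraries, adjusted p = 0.0205 in the same edgeR test), a call that ended with DESeq2, the Trdc gate, Scrublet calls removed, thinned sums, a tag share of 90%, type 17-like clusters, no replicate block, male or female pools alone, and without colon or the second hashtag set. These were 2 of 10488 genes tested. Since libraries of one hashtag set may share mice, both adjusted p-values may be too small. The next smallest p-values are given as values. They belonged to Slamf7, a receptor of lymphocytes (0.62 ± 0.14), Slc16a10, an amino acid transporter gene (0.42 ± 0.088), Cd7 (-0.29 ± 0.061, lower in 9 of 9 libraries) and Ly86 (-0.51 ± 0.12). All 4 tested members of the region list were higher, with 2 past the threshold adjusted over the list alone (camera adjusted p = 0.00068, adjusted p = 0.294 with an estimated correlation, fry adjusted p = 0.116). Ube3a had a log2 change of 0.37 ± 0.10, Snrpn 0.34 ± 0.21, Herc2 0.26 ± 0.096 and Atp10a 0.05 ± 0.076. Of 14 glycolysis genes 12 were higher (adjusted p = 0.0434, adjusted p = 0.725 with an estimated correlation), with Slc16a3, a lactate exporter gene, at 0.26 ± 0.11 and Hk2 at 0.21 ± 0.097. Without the second hashtag set, whose female pools contradict their labels, 4 genes passed, each in 6 of 6 libraries, Ube3a (0.65), Tsc22d3, a glucocorticoid-induced leucine zipper gene (-0.56), Herc2 (0.54) and Cd7 (-0.40), and the region list passed with an estimated correlation (adjusted p = 0.0439). That set was left out because of its region values, so for Ube3a, Herc2 and the region list this is no separate test. The count was 1 with DESeq2 and 0 with no replicate block (14 at an unadjusted p under 0.05). Leaving out 1 library gave 2 to 9 genes, with 9 without spleen, 7 without blood, 7 without brain library 2, 6 without lung, and 4 without brain library 3 or thymus.

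In brain, 5 genes passed in edgeR between the labelled genotypes, Tsc22d3 and 4 receptor segments. Tsc22d3 was at 257 CPM in WT and 162 in 15q cells (mean of 3 libraries), a log2 change of -0.69 ± 0.13 (SE, lower in 2 of 3 libraries, adjusted p = 0.0182 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The receptor segments, chosen after their values were seen, were Trbv15 (4.14), Trdv1 (2.10), Trav13-4-dv7 (1.42) and Trbv12-2 (-2.54), each with the same direction in 3 of 3 libraries. These were 5 of 7589 genes tested. Among the smallest p-values that did not pass, Mfsd10, a transporter gene, had 0.81 ± 0.18, Il6st, the shared receptor chain of interleukin 6 cytokines, -1.27 ± 0.31, Lrmp -0.998 ± 0.25 and Arhgef18 -0.67 ± 0.17. All 3 tested region members were higher and past the threshold adjusted over the list alone, Herc2 (0.55 ± 0.16), Atp10a (0.53 ± 0.25) and Ube3a (0.53 ± 0.15), with camera adjusted p = 0.0353, adjusted p = 0.966 with an estimated correlation and fry adjusted p = 0.345. Brain libraries 1, 2 and 3 come from different hashtag sets, and the count was 13 without library 1, 0 without library 2 (257 at an unadjusted p under 0.05) and 15 without library 3. Sex was not a term of the fit. The female share of cells in WT and 15q was 23.0% and 36.8% in library 1, and 21.8% and 34.3% in library 2. It was 51.7% and 22.9% in library 3, and the genes called without library 3 included Xist. DESeq2 called 0 (17 unadjusted), and edgeR 0 in female pools (196 unadjusted) and 1, Trbv15, with no replicate block. The Tsc22d3 call also ended at a tag share of 90%. Of the segments, the calls of Trbv12-2, Trdv1 and Trav13-4-dv7 also ended in type 17-like clusters, those of Trdv1 and Trav13-4-dv7 in male pools, that of Trav13-4-dv7 at a tag share of 90% and without library 3, those of Trbv15 and Trbv12-2 with thinned sums, and those of Trbv15, Trbv12-2 and Trav13-4-dv7 with the Trdc gate.

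The genotype difference differed between brain and the other tissues for Il22, which encodes a cytokine acting on epithelia, in 1 of 10488 genes (adjusted p = 0.0358 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was at 83.6 CPM in WT and 0 in 15q cells of brain library 3 and at 0 in both genotypes of brain libraries 1 and 2. The call rests on brain library 3. Without it no brain sum held Il22, so the fitted log2 difference of 0.40 is no estimate for brain. As values, Klra1 had a log2 difference of -4.77 ± 1.05, Runx2, a transcription factor gene, -0.91 ± 0.21, Alcam -4.48 ± 1.10 and Lrmp -0.94 ± 0.23. None of the 16 lists passed camera, the smallest adjusted p being 0.0938 for the interferon list. DESeq2 called 0 genes (341 unadjusted). Leaving out dura, blood, thymus or lung also gave 0 (571, 432, 570 and 429 unadjusted), leaving out brain library 1 or 3 gave 2, and the fit with no replicate block gave 0 (71 unadjusted).

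Within single tissues, the named gene with the largest genotype ratio was Nr4a1 in thymus. It was at 19.4 CPM (11.1 to 31.6) in 15q and 190 (158 to 225) in WT cells of thymus, and Egr1, another immediate early gene, at 17.0 against 88.2, from 1 library without a replicate check. Serpine2 was lower in 15q cells (18.2 against 77.9), and Kctd10 (47.4 against 11.8), Anxa1 (42.5 against 10.3) and Dynll2 (57.1 against 19.1) were higher. Of these thymus cells, 86 of 131 were type 17-like in 15q and 45 of 100 in WT. Whether this mix of cells moves the values was not tested. In dura, 15q cells held more Cd40lg, a T cell help ligand (48.6 against 9.60), Ccdc162 (60.0 against 14.4) and Ccnb1ip1 (377 against 132), and less Ccl5, a chemokine (24.3 against 106), Stk3 (14.3 against 57.6) and Nfkbiz (21.4 against 67.2). In spleen Ccl5 was higher (86.1 against 31.6), with Mcm2 (31.8 against 11.3) and Anxa1 (144 against 76.5), while Ly6a (176 against 360), Bhlhe40 (11.95 against 41.4) and Serpina3g (10.2 against 29.3) were lower. In blood Klra1 (22.7 against 7.58) and Cd74 (56.2 against 31.0) were higher and Il17f (24.5 against 47.9), Cd8b1 (18.6 against 40.7) and Clstn3 (4.13 against 11.7) lower, and Xist (89.9 against 46.5) was higher where the female share of cells was 39.7% in 15q and 21.6% in WT cells. In lung Ccl4 (18.2 against 3.57), Cxcr3 (88.6 against 56.3) and Ret (44.5 against 26.6) were higher and Gzmb (108 against 189), Slc15a2 (41.7 against 86.3) and Nccrp1 (18.3 against 31.6) lower. In colon Ccl4 (126 against 72.3), Xcl1 (27.7 against 15.9) and Ifng (22.9 against 12.8) were higher and Gzmb (323 against 559), Slc15a2 (48.5 against 109.0) and Serpine2 (25.7 against 49.3) lower. The female share also differed in spleen (16.5% in 15q, 41.1% in WT) and dura (44.4% and 27.1%). In male and in female pools taken apart the genes of this paragraph kept these directions, except Stk3 and Ccl5 of dura, Serpine2 of thymus and colon and Ly6a of spleen in female pools, and Slc15a2 of lung and colon and Xcl1 of colon in male pools. Lung and colon belong to the second hashtag set, whose female pools contradict their labels.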

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

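The tests of explanations and the counts of other splits in this part were all specified after the results they bear on had been seen, and the paragraphs on single libraries use a rule that was fixed beforehand.

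The region difference between genotypes ran against the label in the female pools of the second hashtag set (lung, colon and brain library 1). Their mean log2 ratio was -0.51, that of the 6 other female pools 0.42, a difference of -0.93, for which no p-value is given, since the set was singled out by these values and its libraries may share mice. A sex effect on the region as the source of the reversal is argued against by those 6 pools at 0.4222 (SD 0.28), and mixing of cells between pools, which moves a ratio towards that of the males, by the upper 95% bound of the lung female ratio at -0.48098. An exchange of the WT and 15q female tags in the label table may be the source, but the mean of -0.50857 is the value that raised the question and does not test it. In lung, colon and brain library 1, pools labelled WT female held 259, 297 and 237 CPM of the region list. Their males labelled 15q held 240, 304 and 239. Pools labelled 15q female held 173, 217 and 168, and males labelled WT 162, 223 and 198. An exchange would give such levels, but they come from the same pools and are no separate test. Genes outside the region did not decide on an exchange (rho = -0.11535 across 109 genes, which are not independent replicates, permutation p = 0.239). Slc15a2 kept its labelled direction in these pools but cannot decide it either. It was named from a test that included them, was not called without the second set, and may not follow the genotype. No cell was relabelled. A smaller sex difference stays open, since the female ratio minus the male ratio was -0.22 ± 0.33 outside the second set (SD, n = 6, lower in 5 of 6, exact p = 0.156).

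The immediate early list was lower in brain than in lung and colon. That the difference lies in gamma-delta T-like cells alone is argued against by B-like cells, whose list was higher in lung than in brain by a log2 ratio of 0.93463. RNA from gamma-delta T-like cells does not account for this, since Il17a put it at 7.12% of their level in lung and the list without it was at 8530 CPM in B-like cells, above the highest upper bound of a brain library (5485). The hashtag set shared by lung and colon is argued against by brain library 1 of the same set, which lay above the other brain libraries by a log2 ratio of only 0.026835, while lung lay above brain by 1.54. A response to enzyme digestion during preparation and a difference of tissue may each be open causes, since dura and colon were digested per the labels, brain was not stated to be, and no value here parts them from the tissue.

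Slc15a2 was lower in labelled 15q cells of female pools and not of male pools. Its log2 ratio was -1.71 ± 0.98 in female pools (SD, n = 9 libraries, lower in 8 of 9, exact p = 0.00781) and 0.22061 ± 0.52 in male pools (SD, n = 9), so the female ratio minus the male ratio was -1.93 (exact p = 0.00391, below 0 in 9 of 9 libraries). Libraries of one hashtag set may share mice, so the 9 are perhaps not independent and both p-values may be too small. The gene was picked by its p-value in a test on these same cells, and the split by sex was added after the data were seen. Neither p-value is therefore a separate test. The male value argues against an effect of the duplication in both sexes. A level set by the region's dosage is argued against by the female pools of the second set, where the region ratio was below 0 and that of Slc15a2 -2.53 ± 0.27, and a shift of its neighbourhood by the median of 0.09706 for 15 genes within 1 Mb (SD 0.18, from -0.28 to 0.33). An inherited variant or litter difference carried by the mice of the female pools might be the source and was not tested, and sex itself stays open.

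Among 9 libraries, brain library 3 lay far from the others in the log2 ratio of labelled 15q over WT of Slc16a10 (-1.28, the nearest being colon at 0.23), Il22 (-6.40, thymus -1.32) and Klra1 (-4.29, brain library 2 -0.89). Among the 6 other tissues, colon lay far above the rest in summed CPM of the tissue residency list (8576, lung 4258), the checkpoint list (3510, lung 1428) and the cytokine list (8804, lung 3457). Thymus lay apart in the interferon list (1911, blood 1130) and spleen in the oxidative phosphorylation list (13052, blood 9347). The rule was applied to 45 groups and marked 8, where chance alone marks about 2.25 in independent groups. The groups were not independent, since some lists share genes, and Il22 and Klra1 were named from a test on the same libraries. The 2 numbers therefore do not show an excess. The Il22 difference between brain and other tissues had an adjusted p of 0.0358 in edgeR's quasi-likelihood test and rests on brain library 3.

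Counts of other splits bear on each count of genes. For brain against other tissues the real count was 0 in edgeR (552 unadjusted) and in DESeq2 (709), which each of 84 choices of 3 libraries reaches by definition, so it says nothing about chance. The highest other was 490 for blood, lung and colon, which points to a structure of the samples. In type 17-like clusters with the hashtag set as a term, 3 of 27 choices gave at least the 2 real genes (highest other 13, dura with brain libraries 1 and 3), so chance is not excluded. For 15q against WT over all libraries, 23 of 100 drawn exchanges within libraries gave at least 2 genes (highest other 13), so chance is not excluded. In brain, 2 of 4 exchanges gave at least 5 (highest other 5), too few exchanges for a share under 0.05. For the interaction, 50 of 84 choices gave at least 1 gene, with 41 for brain library 3, thymus and spleen, which form the third hashtag set. A fit without that set was not run. Without brain library 3 the count was 2. Without the second hashtag set, 2 of 32 exchanges gave at least the 4 real genes (highest other 4), so chance is not excluded. In male pools 4 of 100 gave at least the 14 real genes (highest other 16), a share under 0.05.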

How the results depend on the processing

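Settings that leave out the second hashtag set or use male pools, female pools, type 17-like clusters, the unnamed thymic cluster or the hashtag set as a term were chosen after seeing the data. The others were planned. Of 761 recomputed values 593 stayed the same, 75 were weaker, 43 stronger, 2 reversed, and 48 without a test moved by more than their spread. For named genes and lists these words refer to direction and side of the threshold (44 weaker, 20 stronger and 2 reversed). A count of genes or lists was weaker or stronger where it fell or rose beyond a set fold, or left 0. For brain against other tissues, edgeR gave 0 genes under each single setting (268 to 1388 unadjusted) and DESeq2, run without any other change, 0 (709 unadjusted), while edgeR gave 2 where type 17-like clusters and the hashtag set as a term were combined. The cause of the changes below was not tested.

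For 15q against WT over all libraries (2 genes) the count was 1 with DESeq2, with Scrublet calls removed, with a tag share of 90% and in type 17-like clusters, 21 without a filter on low counts, 8 with the Trdc gate, 4 with thinned sums, 4 without the second hashtag set, 14 in male pools, 8 in female pools and 0 with no replicate block (14 unadjusted). In brain (5 genes) it was 0 with DESeq2 (17 unadjusted), 8 without the filter, 20 with the gate, 3 with thinned sums, 4 with a tag share of 90%, 3 in male pools, 0 in female pools (196 unadjusted), 3 in type 17-like clusters and 1 with no replicate block. For the interaction (1 gene) it was 0 with DESeq2 (341 unadjusted), Scrublet (507 unadjusted), thinned sums (337), a tag share of 90% (439), no replicate block (71) and without the second set (367), 9 without the filter, 4 with the gate, 3 in female pools and 2 in type 17-like clusters. Leaving out each library gave 2 to 9 genes over all libraries, 0 to 15 in brain and 0 to 2 for the interaction. The block changed no other call.

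Of the gene lists that passed camera, 0 passed with an estimated correlation and 0 with fry in the brain, genotype and genotype in brain tests. In male pools 5 lists passed camera over all libraries, and with an estimated correlation 1 was left, the region list (adjusted p = 0.0081, fry adjusted p = 0.00027), the other 4 being at 0.506. In female pools 1 passed camera over all libraries (adjusted p = 0.727 with an estimated correlation) and 0 in brain. In male pools Slc15a2 reversed to a log2 change of 0.12. The Il22 difference ran from -10.29 without brain replicate 2 to 0.40, reversed, without brain replicate 3. The latter is no estimate for brain, since no brain sum then held Il22. The region ratio was 0.34 to 0.44 without each library and 0.11 in female pools, where it no longer passed.

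At Leiden resolution 2 the gamma-delta T-like share was 78.3% in thymus and 55.8% in colon. With a tag share of 90% the labelled 15q share was 53.7% in brain library 2, 64.9% in blood, 49.6% in lung and 51.1% in colon. Thinning each cell to 1000 UMIs lowered Tcrg-V6 to 76.3%, 38.8% and 43.4% in brain libraries 1, 2 and 3, 48.5% in dura, 14.5% in blood, 77.9% in thymus, 80.5% in spleen, 65.2% in lung and 69.7% in colon, which follows from fewer UMIs per cell. Of 417 values of named genes and lists 351 stayed, and of 162 values of tissue genes 129 stayed inside their interval. Depth limits dura and brain libraries 1 and 3, with 169, 180 and 198 gamma-delta T-like cells.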

Other observations

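The gene names and values in this part were chosen after the data were seen, and its tests of a difference in cell shares were not planned.

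The immediate early list was also lower in brain library 2 than in lung in NK-like, CD8 T-like and CD4 T-like cells. In NK-like cells it was at 4803 CPM in brain library 2, 6085 in dura, 7520 in blood and 7753 in lung (95% interval 7116 to 8430, 18 cells with Il17a at 184 CPM). In CD8 T-like cells it was at 2888 in brain library 3 (10 cells), 3866 in spleen, 4749 in brain library 2, 4848 in dura (95% interval 4632 to 5071), 6312 in blood and 7251 in lung. In CD4 T-like cells it was at 4645 in brain library 2, 6322 in dura and 9339 in lung. Fos in NK-like cells was at 7.04 CPM in brain library 2 and 162 in dura.

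Next to the duplicated segment, Nipa1, a magnesium transporter gene (chromosome 7, 55977567 to 56019954, mm10), had 61 UMIs in 15q against 13 in WT gamma-delta T-like cells of the first and the third hashtag sets, a log2 ratio of 1.73 (95% interval 0.85 to 2.72). Over all kept cells of these sets it had 295 against 94 UMIs (log2 ratio 1.25), while its neighbour Nipa2 had 0.022. Over the same cells Ndn had 108 against 20 UMIs and Mkrn3 59 against 7, log2 ratios of 2.03 and 2.68, both above those of Herc2 (0.57) and Ube3a (0.53).

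In male pools, Ube3a (log2 change 0.70, higher in 9 of 9 libraries), Herc2 (0.45, higher in 9 of 9), Rbm3, a cold-inducible RNA binding protein gene (0.25, higher in 9 of 9), and Ccr6, a chemokine receptor gene of type 17 cells (-0.46, lower in 9 of 9), passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p of 7.8e-10, 0.000208, 0.0194 and 0.00903. Slc16a10 was higher in 8 of 9 (0.66) and Ccl4 in 5 of 9 (2.40). In female pools Trdv1 (1.66, higher in 7 of 9 libraries), Tnfsf11 (0.76, 6 of 9) and Ramp1 (0.33, 8 of 9) were higher and Slc15a2 (-2.22) and Mxi1 (-0.53) lower (8 of 9 each), by labels that the region contradicts in 3 of the 9 libraries, lung and colon among them, which hold most of the female gamma-delta T-like cells.

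Whether genotype moves the share of type 17-like cells was tested, and the difference did not pass. The labelled 15q share minus the WT share was 2.44 percentage points ± 4.72 (SD, n = 9 libraries, higher in 5 of 9, exact permutation p = 0.199), with 11.6 points in thymus and -4.32 in brain library 1. Without the second hashtag set it was 3.87 ± 4.66 points (SD, n = 6, higher in 4 of 6, exact permutation p = 0.125), and in brain 0.24 ± 4.09 (SD, n = 3, p = 0.75).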
